A study of Mus musculus with 2 samples.

How the data were processed

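Small RNA libraries (RNA shorter than 30 bases, per the labels) were made from single neural tubes of 2 newborn pups of 1 dam. The biological replicate numbers 1 and 2 of the labels belong to pup 1 and pup 2. The sex of the pups was not collected.

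The authors deposited raw counts per miRNA gene for each library, on either strand, on the gene's own strand and on the opposite strand. Per the text deposited with the tables, the genome was mm10 and the annotation GENCODE M4. The aligner and the counting program are not given in the sources used here. Each table opens with read classes that name no gene (unmapped, multimapping, outside features, ambiguous). These classes stayed out of library totals and took 10.9% (unmapped), 35.5% (multimapping) and 1.79% (outside miRNA genes on either strand) of the reads; no read was ambiguous. The gene counts therefore leave out reads that fitted several places; how far this affects miRNAs made by several similar genes was not measured. Counts are per precursor gene, so the arms of a precursor are not told apart.

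Own-strand counts were used throughout, because the deposited text names no column as the quantification. Totals were 3216453 and 3660693 counts, so 1 count equals 0.311 CPM in pup 1 and 0.273 CPM in pup 2, and a count of 0 allows up to 3 counts. CPM is 1000000 times the count over the own-strand total. A gene was detected with at least 10 counts in both pups. Gene symbols, positions and surrounding genes came from GENCODE M21, which uses the same genome build, matched by Ensembl identifier for 1894 of 1973 genes; the 79 others had at most 2 counts. Shared stretches of 22 bases were searched between the annotated precursors.

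Means and SDs are over the 2 libraries. Genes were called different in level where mean log2(CPM + 1) differed by more than 1.96 pooled SDs, pooled within 4 classes of abundance. These SDs hold differences between the pups only, and no bias between genes that both libraries share. The pairs compared were the successive ranks of the 20 most abundant genes and the first and second member of each list. This rule for pairs was set after the data had been seen and replaced a shorter list of pairs picked by hand, all of which had differed beyond the spread. Of the 17 list pairs, 13 differed and 4 did not.

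The pups were compared gene by gene with an exact two-sided binomial test, given their totals, for genes with at least 10 counts summed, with Benjamini-Hochberg adjustment at 0.05. Log2 ratios had 0.5 added to each count. A list's shift was its median log2 ratio, placed among 10000 random lists of the same size drawn within 10 classes of mean expression, and called at or beyond percentiles 2.5 and 97.5. The dispersion came from edgeR with an intercept only. Smallest p-values were limited to 1e-300. On simulated counts with counting error alone, the binomial test called 72.0% of 50 genes changed 2-fold and 90.0% of 50 changed 4-fold, and 2.4% of unchanged genes. With variation between libraries added at the coefficient estimated from these same pups, it called 44.2% of unchanged genes. Both simulations used totals of the unchanged genes, whereas the pups were compared on totals of all genes. The simulated rates therefore hold no error from changed genes moving the totals. A planted log2 shift of 0.5 in 8 genes reached percentile 100, and 6 of 100 lists with no shift were called. That simulation drew genes independently with 1 common spread, so its rates need not hold for lists of neighbouring genes.

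The 19 lists, the tests, the alternative settings and the rule for named genes were fixed before the data were examined. The rule takes the 20 genes of highest mean CPM, the 3 highest members of each list (all members of lists of 4 or fewer), and the 5 largest log2 ratios in each direction among called genes with at least 100 counts in each pup, 64 genes in all. Genes named outside it were chosen after their values were seen. This holds for the families with several gene copies, for Mir302c and for the genes at loci with opposite-strand counts. It also holds for Mir679 and for the further abundant genes outside the lists, such as Mir22 and Mir30a. Of 197 list members, 178 were measured; 3 symbols were matched through other names after the tables were seen.

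Alternatives were TMM and DESeq2 scaling, other count minimums and pseudocounts, either-strand counts, leaving out each pup, and leaving out the most abundant gene. Alternatives chosen after seeing the data were shared stretches of 20 and 18 bases and list shifts without members sharing 22 bases. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.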

Results

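MicroRNA (miRNA) genes were profiled by small RNA sequencing in the neural tube of newborn mice (postnatal day 0, strain B6NCrl). The data comprised 1 group of 2 libraries, from single neural tubes of pup 1 and pup 2 of 1 dam. With 1 group, no comparison between conditions existed, so the values describe the tissue and the difference between the 2 pups. The pups were littermates, and the spread given after each mean is the SD over these 2 libraries (n = 2).

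Most uniquely placed reads fell in miRNA genes. Of 6362751 reads of pup 1 and 7212044 reads of pup 2, 3216453 and 3660693 were counted to a miRNA gene on its own strand, a share of 50.7% ± 0.15 (SD, n = 2). Reads that fitted several places made up 35.5% ± 0.15 and were not counted to any gene. Unmapped reads made up 10.9% ± 0.11, reads placed once outside miRNA genes 1.79% ± 0.14, and reads opposite to a miRNA gene 1.11% ± 0.031. Exact 95% binomial intervals of the own-strand share were 50.5 to 50.6% in pup 1 and 50.7 to 50.8% in pup 2. Intervals and detection limits cover counting error only, since the reads carried no stated molecular identifiers.

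Of 1973 miRNA genes, 352 had at least 10 counts in both pups. No counts were found in either pup for 1293 genes, which allows up to 0.933 CPM (counts scaled to 1000000 own-strand counts per library) in pup 1 and 0.820 CPM in pup 2. These limits hold for uniquely placed own-strand reads only, since reads that fitted several places were not counted. A mean of 1000 CPM or more was reached by 95 genes, and 10000 CPM or more by 15 genes.

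Among uniquely placed own-strand counts, the highest values belonged to 2 miRNA genes of the Hox clusters, whose protein genes set position along the body axis. Mir10b reached 180670 CPM ± 9672 (SD, n = 2) and Mir10a 135960 CPM ± 5935, followed by Mir99a at 105960 CPM ± 5461. These 3 genes held 43.7% of the counts in pup 1 and 40.8% in pup 2, and the 20 most abundant genes held 73.6% and 72.2%. Mirlet7g (46050 CPM ± 4761), Mir487b (36092 CPM ± 1520), Mir126a (26923 CPM ± 1294), Mir335 (26373 CPM ± 435) and Mirlet7i (25594 CPM ± 815) came next. Mir137, a miRNA of neurons, stood at 16076 CPM ± 1484.

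**Figure D1:**
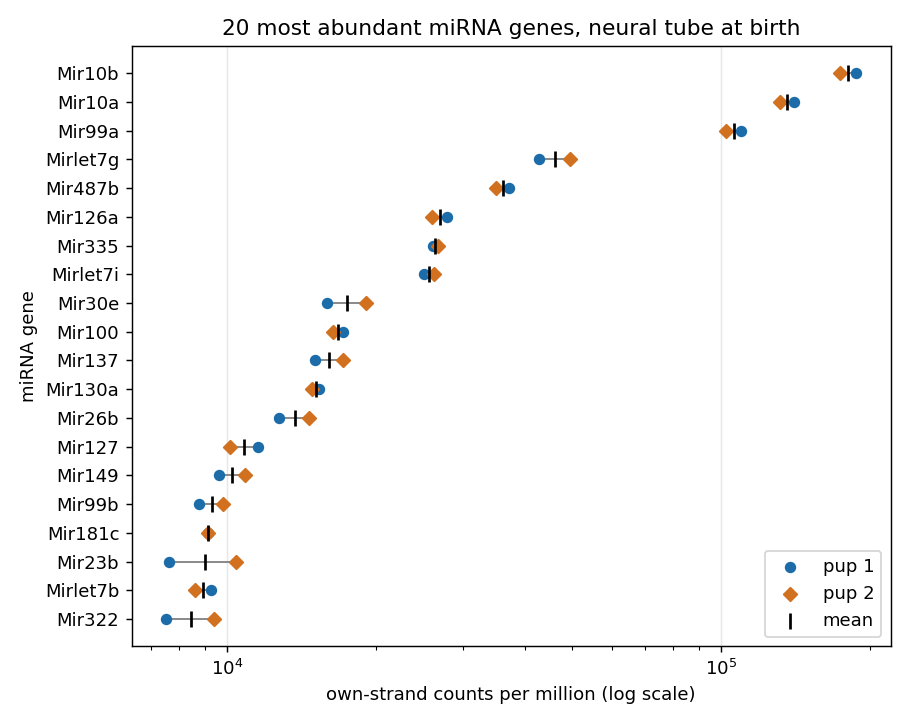
Own-strand CPM (log axis) of the 20 most abundant miRNA genes in pup 1 (circles) and pup 2 (diamonds), with the mean of both as a vertical tick. Mir10b, at 180670 CPM on average, lies at the top and Mir322, at 8465 CPM, at the bottom of the 20 genes.

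Mir10b lay 1.33-fold above Mir10a, Mir10a 1.28-fold above Mir99a, and Mir99a 2.31-fold above Mirlet7g, each by more than the limit set by the pooled SD of genes of like abundance. Further down the ranking the genes were closer. Of the 19 pairs of successive ranks among the 20 most abundant genes, 7 differed by more than this spread and 12 did not, among them Mir126a against Mir335 (1.02-fold) and Mir137 against Mir130a (1.06-fold). Mir10a and Mir10b make closely similar mature miRNAs, as do Mir99a and Mir100, so the split of reads within these pairs is uncertain. The pooled SD measures only differences between the pups, so a bias between genes that both libraries share is not covered. The same holds for the other folds between genes given below.

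Mir10b lies on chromosome 2 (74726070 to 74726137, plus strand, mm10), in introns of Hoxd3 and Hoxd4 in the GENCODE annotation. Mir10a lies on chromosome 11 (96317165 to 96317274, plus strand), with no annotated gene around it on that strand. Mir99a lies on chromosome 16 (77598936 to 77599000, plus strand), in an intron of the noncoding gene Mir99ahg. Mirlet7g lies on chromosome 9 (106178840 to 106178927, plus strand), in an intron of Wdr82. Mir487b lies on chromosome 12 (109727333 to 109727414, plus strand), and Mir137 on chromosome 3 (118433857 to 118433929, plus strand), in an exon of the noncoding gene Gm26871.

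The 6 miRNA genes of the Hox clusters together held 32.8% ± 1.82 of the counts (SD, n = 2), and all 6 were detected. Without Mir10b in list and total, the share was 18.05%. Of all reads they held 17.3% in pup 1 and 16.0% in pup 2, and families in the uncounted multimapping reads cannot be ranked against them. Besides Mir10a and Mir10b, Mir196b, in an exon of Hoxa9, reached 5576 CPM ± 1863. The miR-99/100 and miR-125 genes held 13.9% ± 0.50, with Mir100 at 16784 CPM ± 553 and Mir99b at 9295 CPM ± 744. The imprinted Dlk1-Dio3 region of chromosome 12, a large cluster of maternally expressed miRNA genes, held 10.5% ± 0.31, and 44 of its 50 measured members were detected. Mir487b lay 3.34-fold above Mir127 (10836 CPM ± 1027), and Mir382 stood at 7336 CPM ± 354. The let-7 family, which rises as tissues mature, held 9.25% ± 0.71 with 10 of 10 measured members detected. Mirlet7g lay 1.79-fold above Mirlet7i, and Mirlet7b stood at 8935 CPM ± 484. Reads that may belong to unmeasured members of the Dlk1-Dio3 and let-7 lists, such as Mir376a and Mirlet7e, are not in these shares.

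Among lists named for cells of the nervous system, the neuronal list held 3.11% ± 0.30 of the counts (SD, n = 2), with 18 of 21 measured members detected. Mir137 lay 5.17-fold above Mir128-1 (3126 CPM ± 520), the next member, and Mir153 stood at 1838 CPM ± 74.3. Mir128-1, Mir219a-2 and both miR-218 genes share a 22-base stretch with another miRNA gene, unlike Mir137 and Mir338, so their counts and the folds against them are uncertain. The list reported in astroglia, whose genes are also used in many other tissues, held 3.08% ± 0.48, led by Mir26b (13709 CPM ± 1346), Mir23b (9022 CPM ± 1972) and Mir23a (5870 CPM ± 1499). The oligodendrocyte list held 0.204% ± 0.026, and Mir338 (1048 CPM ± 105) and Mir219a-2 (925 CPM ± 155.1) did not differ beyond the pooled spread. The proliferation list, made of the miR-17-92 cluster and its relatives, held 1.53% ± 0.025, with Mir17 at 5069 CPM ± 240, Mir106b at 2988 CPM ± 368.97 and Mir93 at 2578 CPM ± 30.5. The miR-218 genes of motor neurons held 0.0313% ± 0.0017, with Mir218-2, in an intron of Slit3, at 276 CPM ± 12.8 and Mir218-1, in an intron of Slit2, at 36.5 CPM ± 4.07. The pluripotency list held 0.0076% ± 0.0035, and 4 of its 12 measured members were detected, Mir302a to Mir302d.

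Markers of other tissues that a dissected neural tube could hold, within it or attached to it, were also measured. The counts do not tell these 2 cases apart. Endothelial Mir126a, in an exon of Egfl7, held 2.69% ± 0.13 of the counts (SD, n = 2), and the mesenchyme list held 1.11% ± 0.050, led by Mir143 (6977 CPM ± 144.9) and Mir140 (3368 CPM ± 214.3), with Mir214 at 457 CPM ± 147. The miR-183 cluster of sensory neurons and sensory organs held 0.431% ± 0.153, with Mir182 at 2695 CPM ± 1072, Mir183 at 1062 CPM ± 252 and Mir96 at 556 CPM ± 202.99. The immune list held 0.0664% ± 0.0052 (Mir150 at 207 CPM ± 8.62, Mir223 at 186 CPM ± 51.5) and the epithelial list 0.0518% ± 0.0027 (Mir203 at 449 CPM ± 14.3). Mir142, a fixed member of the immune list, was not measured as a gene of its own, so its reads are not in that share. The pancreas list held 0.0287% ± 0.0013, the erythroid list 0.0140% ± 0.0017, the striated muscle list 0.0111% ± 0.0030 and Mir122 of hepatocytes 0.0084% ± 0.0028. Mir451a of red blood cell precursors stood at 108 CPM ± 22.02, and Mir206 of skeletal muscle at 85.6 CPM ± 23.03.

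**Figure D2:**
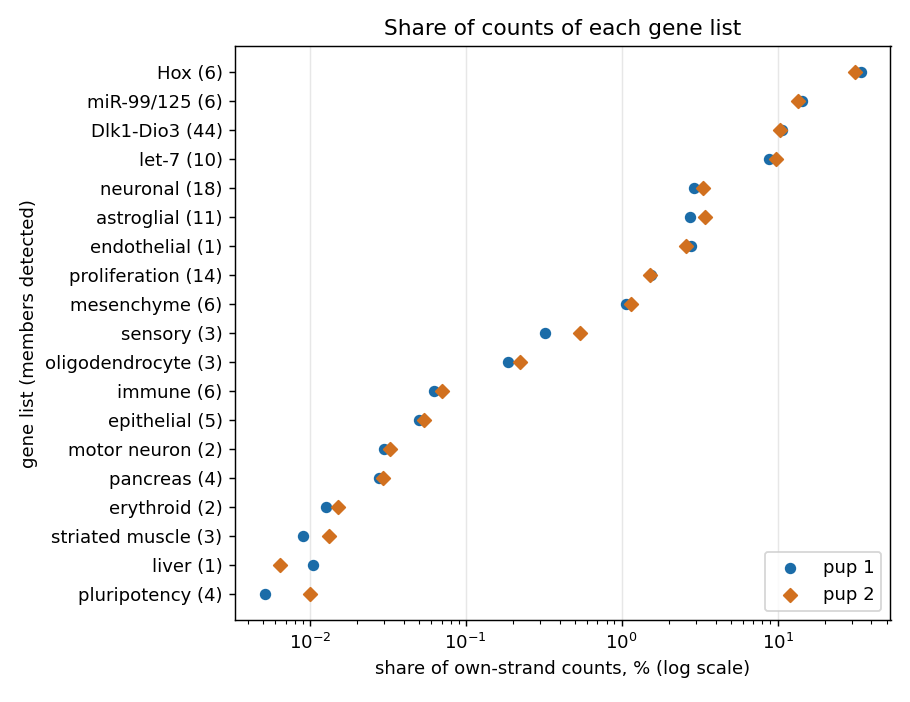
Share of own-strand counts in percent (log axis) of each of the 19 gene lists, with the number of detected members in brackets, in pup 1 (circles) and pup 2 (diamonds). The Hox list holds 32.8% on average and the pluripotency list 0.0076%.

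The pups had closely similar profiles. Across the 352 detected genes, log2(CPM + 1) of pup 1 and pup 2 had a Pearson r of 0.995 and a Spearman rho of 0.994; these are correlations across genes, which are not independent replicates. Of these genes, 310 (88.1%) lay within 1.5-fold, the SD of the log2 ratio was 0.35, and edgeR's common biological coefficient of variation was 14.2%. The libraries were nevertheless not 1 library deposited in duplicate. An exact two-sided binomial test with Benjamini-Hochberg adjustment found 167 of 413 tested genes to differ in share, 105 higher and 62 lower in pup 2, of which 31 differed by at least 1.5-fold and 7 by at least 2-fold. This test compares 2 libraries and measures counting error only. The data hold no estimate of the variation between libraries that is independent of these pups, so whether the 167 calls (40.4% of the tested genes) exceed it was not tested.

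Among genes with at least 100 counts in each pup, the highest ratios in pup 2 were those of Mir182 (log2 ratio 0.83), Mir351 (0.83), Mirlet7a-1 (0.83), Mir96 (0.76) and Mir181b-2 (0.75). The lowest were those of Mir129-1 (-0.79), Mir122 (-0.70), Mir196b (-0.69), Mir30b (-0.64) and Mir1249 (-0.59). Each passed the exact binomial test; the adjusted p was 5.3e-113 for Mir351, 2.2e-17 for Mir30b and 2.3e-05 for Mir1249. Mirlet7a-1, Mir181b-2 and Mir129-1 share stretches of 22 bases with other miRNA genes, so their counts are uncertain.

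By list, all 6 Hox miRNA genes were called lower in pup 2, and the same 6 when adjusted over the list alone. Their median log2 ratio was -0.29, below all of 10000 random lists matched on expression. It was -0.14 (percentile 0.51) over the 4 members that share no 22-base stretch and -0.18 (percentile 0.56) with a minimum of 50 counts. Mir10b (log2 ratio -0.11) and Mir10a (-0.09), which held most of the list's counts, lay above the list's median of -0.29. The list's share of counts had a log2 ratio of -0.11. All 3 sensory genes were called higher (3 adjusted over the list alone), with a median of 0.76 at percentile 99.8. In the let-7 family 9 genes were called higher and 1, Mirlet7b, lower (9 and 1 adjusted over the list alone), with a median of 0.24 at percentile 98.8. Over the 5 let-7 members that share no 22-base stretch with another miRNA gene, the median was 0.17 at percentile 78.7, which ends that call. The 4 detected pluripotency genes had a median of 0.84 at percentile 99.6 and 3 were called higher, on as few as 25 counts in a pup (Mir302b); Mir302c, with 11 and 22 counts, was not called. The Dlk1-Dio3 genes had a median of -0.05 at percentile 1.03, with 8 called higher and 12 lower (8 and 13 adjusted over the list alone); the median was -0.09 with TMM or DESeq2 scaling. The sensory genes form 1 genomic cluster, as do the 4 pluripotency genes, and the Dlk1-Dio3 genes are packed in 1 region of chromosome 12. Neighbouring genes deviated together (r = 0.27 over 90 pairs), whereas the random lists treat genes as independent draws.

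The medians of the other lists lay within the percentile bounds for a call. The astroglial list was at percentile 97.1 (median 0.24, 5 called higher and 2 lower), the striated muscle list at 90.2, the neuronal list at 75.8 (9 higher, 3 lower), the oligodendrocyte list at 74.0, the mesenchyme list at 70.7 and the epithelial list at 65.5. The immune list was at 62.7, the pancreas list at 43.6 with none of 4 genes called, the list of miR-99 and miR-125 genes at 27.3 (3 higher, 3 lower) and the proliferation list at 13.7. Of the 15 lists examined 5 were called, against 0.75 due by chance if genes were independent draws.

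**Figure D3:**
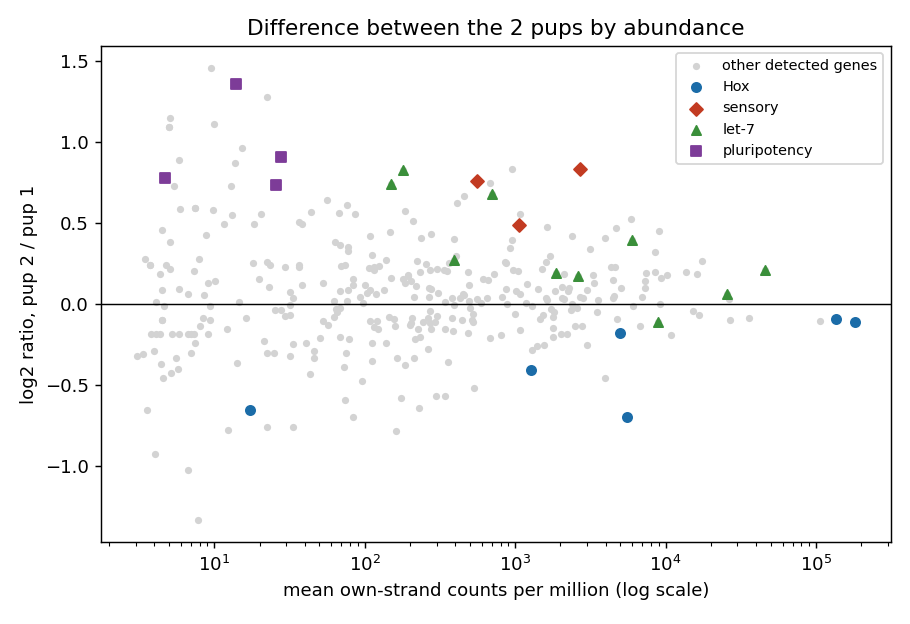
Log2 ratio of pup 2 over pup 1 against mean own-strand CPM (log axis) for the 352 detected miRNA genes, with the Hox, sensory, let-7 and pluripotency lists marked. All 6 Hox genes lie below 0 (median -0.29) and all 3 sensory genes above 0 (median 0.76).

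Several miRNAs known from the nervous system had few counts where more than 1 gene makes them. The 3 Mir124a genes together had 13.4 CPM ± 5.35 (SD, n = 2), the measured Mir9 genes 461 CPM ± 13.9 and the Mir26a genes 31.4 CPM ± 3.92, against 13709 CPM for Mir26b, which shares no 22-base stretch. The Mir133a genes had 0 counts in both pups. Other families with copies had more counts, including Mir128 (3994 CPM ± 627), Mir125b (2800 CPM ± 89.0) and Mir138 (2719 CPM ± 671). Genes that share a 22-base stretch with another miRNA gene held 3.32% ± 0.20 of the counts, and 9.47% or 20.2% where the shared stretch was set at 20 or 18 bases. Because reads that fit several places were not counted, the values of such families cover only uniquely placed reads and are not levels of the mature miRNA.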

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

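The tests in this part were chosen after the results were seen. At 11 loci the opposite-strand counts, which are not part of the gene levels in the report, exceeded the limit that a count of 0 allows, while the own-strand counts were at most 2 in a pup. Over both pups the opposite-strand counts were 44405 at Gm25252, 28218 at Gm25927, 22804 at Gm24321, 20369 at Gm24083 and 14589 at Gm25301. They were 9046 at Gm25750, 3752 at Mir299b, 3644 at Mir497b, 2512 at Mir142b, 595 at Gm24111 and 90 at Gm25641.

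Libraries without strand information are argued against, because the opposite-strand share over the other miRNA genes was 0.00307%. A candidate explanation is a miRNA gene on the other strand that is not analysed here as a row of its own: 11 of 11 loci overlapped one in GENCODE M21, against 3 of 1201 genes with no counts on either strand. The genes at these places are Mir376a, Mirlet7e, Mir409, Mir191, Mir378a, Mir380, Mir299a, Mir497, Mir142, Mirlet7f-1 and Mir9-1, in the order of the loci above. If the reads belong to them, Mir376a may stand at 6466 CPM ± 189 (SD, n = 2) and Mirlet7e at 4099 CPM ± 82.4, which would rank 27 and 40. No biological explanation was tested, since the design has 1 group.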

How the results depend on the processing

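No called list shift changed direction under the alternatives tried. Among the 167 called genes, the scaling, count-minimum, 2-fold and either-strand alternatives changed 1 sign, that of Mir335 (log2 ratio 0.03). It changed with TMM and with DESeq2 scaling, where Mir335 was no longer called. Count minimums and the 2-fold rule do not alter a ratio, and each scaling moved all log2 ratios by about -0.04. Under these alternatives only small positive ratios could change sign, by construction. Among list medians that were not called, the sign changed for proliferation (-0.05 to 0.01 with the mean log2 ratio), miR-99 and miR-125 (0.01 to -0.03 with TMM or DESeq2 scaling) and pancreas (0.03 to -0.01 with either scaling). Of the values of the main results under alternatives, 174 kept their side of the threshold or stayed within the spread and 22 did not. Of the values of single named genes 344 did so, and the other 6 were CPM values that moved with either-strand counts. Some of these values could not fail. With 2 pups, leaving out 1 moves a mean CPM or share by less than its SD. TMM and DESeq2 scaling cannot move a list percentile or the Spearman rho between the pups, and a pseudocount cannot move that rho. Such values are no evidence of stability. Without the most abundant gene, Mir10b, shares became 18.05% (Hox), 17.01% (miR-99 and miR-125), 12.8% (Dlk1-Dio3), 11.3% (let-7), 3.79% (neuronal), 3.76% (astroglial), 3.29% (endothelial), 1.86% (proliferation), 1.35% (mesenchyme), 0.248% (oligodendrocyte), 0.0810% (immune), 0.0633% (epithelial), 0.0382% (motor neuron), 0.0350% (pancreas) and 0.0171% (erythroid), by construction of the smaller total. With either-strand counts the proliferation share was 1.495%. With no count filter, 553 genes had a count in both pups, and the Spearman rho over genes with any count was 0.938; both follow from the genes of few counts let in. Requiring a 2-fold difference left 7 of the 167 calls, by construction. TMM and DESeq2 scaling each gave 171 calls (93 higher, 78 lower in pup 2), with 12 of the 167 calls ended and 16 new ones. The let-7 median fell to 0.17 over members sharing no 22 bases; the cause was not tested. Genes sharing 20 or 18 bases held 9.47% and 20.2% of the counts, by construction of the shorter stretch. A minimum of 50 counts left fewer than 3 members, and so no shift, for the pluripotency, striated muscle and epithelial lists; the unshared members of the oligodendrocyte list were also fewer than 3. No paired analysis was possible because the series has 1 group. Depth limits the genes near 10 counts. In the least abundant class (means of 3.08 to 27.9 CPM) the pooled SD was 0.36 on the log2 scale, against 0.16 for the most abundant class.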

Other observations

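Abundant miRNA genes outside the lists were led by Mir335 (26373 CPM ± 435, SD, n = 2), in an intron of the imprinted gene Mest, Mir30e (17485 CPM ± 2254), in an intron of Nfyc, Mir130a (15103 CPM ± 330) and Mir149 (10240 CPM ± 897), in an intron of Gpc1. Mir22 stood at 7422 CPM ± 703, Mir21a, in an exon of Vmp1, at 4637 CPM ± 517 and Mir135b at 4482 CPM ± 80.8. In the miR-30 family, Mir30a (8448 CPM ± 808) and Mir30d (7270 CPM ± 509) were far above Mir30b (228 CPM ± 70.8).

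Counts within genomic clusters were unequal, to widely different degrees. The 3 genes of the miR-183 cluster spanned 4.85-fold and the 4 detected Mir302 genes 5.90-fold. In the 30-gene stretch of the Dlk1-Dio3 region (chromosome 12, 109709060 to 109747960) the detected genes spanned 1229-fold, from Mir487b to Mir679. In the miR-17-92 cluster Mir17 lay 172-fold above the lowest of the 4 members that share no 22 bases.

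The following tests were chosen after the results were seen, except those of GC content and of the most abundant genes. For the few counts of Mir124a, Mir9 and Mir26a, reads set aside because they fit several gene copies may be the cause. List members sharing 22 bases had a median of 90.2 CPM (46 genes) against 227.7 CPM for those sharing none. A two-sided permutation test gave p = 0.092, so this difference in medians cannot be told apart from chance. The test sets different miRNAs against each other, so it cannot decide whether these families lost reads. How many of the 35.5% multimapping reads belong to these miRNAs was not measured. No biological explanation was tested.

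For the genes that differed between the pups, where a different amount of sensory tissue alone and the sex of the pups were not tested, GC content of the precursor is argued against by a Spearman rho of 0.0169 across 352 genes. Noise in single genes with no shared cause, as the only source of the differences, is argued against by neighbouring genes deviating together (r = 0.27 over 90 pairs). A one-sided permutation test of the mean product of neighbouring log2 ratios gave p = 0.0033, and p = 0.00037 over 50 pairs outside chromosome 12. Both sets of pairs include the sensory cluster, whose joint shift had already been seen, so the test is not independent of that shift. Whether neighbours of like sequence account for the result was not tested. How many of the calls come from such noise was not tested. With Mir10b, Mir10a and Mir99a left out of the totals, 82.0% of the 167 calls remained and 165 genes were called in all. This argues against these genes as the source of most calls. The share lay close to the bound of 80% set beforehand, so a smaller contribution stays open. Its exact 95% interval (75.4 to 87.5%) spans that bound but treats the calls as independent. They are not, because a change of totals moves all ratios alike. For more attached tissue of every other kind in pup 2, the 28 genes of 8 other-tissue lists went both ways. Some of these lists, such as the endothelial list, may mark cells within the neural tube. The 28 genes had a median log2 ratio of 0.07, with 17 above 0. Of them 10 were called higher (among them Mir214 at 0.67 and Mir223 at 0.57) and 2 lower (Mir122 at -0.70 and Mir126a at -0.10). Whether pup 2 held more attached tissue of every other kind cannot be told by the 2 forms of test tried. The exact permutation p of 0.0467 for the sensory genes against the 28 genes becomes 0.28 when corrected for picking the sensory list among 6. The first form gave a lowest list percentile of 43.6 against a bound of 50.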
